A study of Formica fusca with 37 samples.

How the data were processed

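The deposited values are raw counts of reads per transcript model, 1 file per library, made by the submitters before deposit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.0, aligned with STAR 2.7.10b, handled with Picard 2.18.7 and counted with featureCounts 2.0.6. The notes do not state the genome build, the annotation, the strand setting, the handling of reads shared between models or whether duplicate reads were removed. The values were whole numbers in all 37 files, over the same 33613 models in the same order, and 20173 models were at 0 in every library. Samples, groups, comparisons and alternatives were written down from the labels, before the data were examined.

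The labels describe pools of 10 ants per box collected on day 4 into RNAlater, split into heads and bodies, with RNA extracted by TRI Reagent and some extracts cleaned with a kit when their 260/280 ratio was under 1.8. They do not say which extracts were cleaned. Total counts and the number of models detected after thinning to 3078241 counts were computed per library. No library was a copy of another: among 68 pairs within groups the lowest chi-square per degree of freedom was 14.3. Libraries are named by body part, treatment, food and the replicate number of the labels.

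Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots drawn in Python 3.11.15 with matplotlib 3.10.9. Models were kept by filterByExpr with the groups given (minimum count 10, minimum total count 15, large n 10, minimum proportion 0.7), which kept a median of 99.9% of counts in heads and 99.8% in bodies. Libraries were scaled by TMM, and CPM are counts per library total after that scaling. Each body part had 1 edgeR quasi-likelihood fit of its 4 groups, with robust dispersion, and all 8 groups had a joint fit for head against body and for the differences between body parts (7858 models). P values are two-sided and were adjusted by the Benjamini-Hochberg method over the models tested for each comparison. A model was called at an adjusted p under 0.05, with no minimum fold change. Fold changes are log2, those for the mean over both foods or both exposures give equal weight to either, and the interaction is the pathogen effect on caffeine food minus that on plain food. Standard errors were taken from the estimate and its F statistic. They cover the spread between boxes under the fitted model and do not cover sharing of reads between models.

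A set of 31 gene lists was fixed before any value was seen. Names in the identifiers were assigned to lists after the files were opened and before any test was run, when some planned lists were divided or narrowed to fit the names present. This gave 24 lists, and 10 of the 31 planned ones had no matching name and were left out. Lists of 3 or more tested models were tested with camera on log2 CPM (prior count 2) at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Calls are also given when adjusted over the members of a list alone. The smaller the list and the more its members share reads, the less its test says about loci, so the numbers of loci are given where they differ much.

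Named models were chosen by rule. From each list up to 4 called models with the largest change were taken. Outside the lists the 10 largest rises and falls were taken, or 6 where over 500 models were called, with a mean of at least 1 CPM. Antimicrobial peptides, prophenoloxidase and vitellogenins were given whatever their result. For head against body, examples were left out where a model was at 0 in all or almost all libraries of a body part, since such a fold change has no bound.

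Alternatives fixed in advance were scaling by RLE, no count filter, a filter at 1 CPM (at least 1 CPM in as many libraries as the smallest group), DESeq2, limma voom with quality weights, a replicate block, leaving out each library in turn and a fit of only the 2 groups compared. The filter at 1 CPM was planned as a stricter one but kept more models than the main filter. It kept 8068 against 7034 in heads and 7696 against 6448 in bodies. Alternatives added after the data were seen were a term for the 6 libraries that stand apart, leaving these out, the term together with leaving out body sham plain 03, and counts summed per locus. The 6 libraries were those above the widest gap in the number of models detected at equal depth in each body part, with a gap of 1218 models in heads and 1339 in bodies. They were not tested against the others, because they were picked by a measured value.

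That the head and the body library of a box come from the same ants is stated by the labels, and 17 boxes have both. After removal of group means and of the shift of the 6 libraries, the mean correlation between head and body libraries was 0.178 within boxes and -0.0431 between boxes. For the joint fit the block was the box. Within a body part, the labels give libraries of different groups only a replicate number in common.

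The code was run on simulated counts with the depth and spread of the deposited ones, with about 200 models changed in each comparison. Models were drawn independently, and no shift of the 6 libraries was put in. The false calls and recovered changes below therefore do not cover structure among the libraries. At most 13 unchanged models were called in any comparison. For the mean pathogen effect 86.0% of 4-fold and 41.0% of 2-fold changes were recovered in heads, and 84.7% and 22.2% in bodies. A changed list of 25 models had a camera p of 1.29e-27 over 7034 simulated models, and 5.5% of 200 unchanged lists had a p under 0.05. These lists were random models with no correlation between them, so this does not cover lists whose members are correlated. Up to 100 splits of the libraries into groups of the same sizes, with the real one counted among them, were tested in the same way.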

Results

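RNA was sequenced from pooled workers of the ant Formica fusca that were either sham-treated or exposed to Beauveria bassiana, a fungus that infects and kills insects. Ants of both kinds were fed plain ant food or ant food with 100 ppm caffeine, and 10 ants per box were collected on day 4. Heads and bodies (thorax and abdomen) of a box were pooled separately, so each library stands for 1 box and 1 body part. The title of the series asks whether caffeine helps infected ants to survive; the deposited values are read counts and hold no survival data. Of the 37 libraries, 19 were of heads (sham plain 5, exposed plain 4, sham caffeine 5, exposed caffeine 5) and 18 of bodies (sham plain 5, exposed plain 4, sham caffeine 4, exposed caffeine 5). Replicates were boxes, and the labels do not say whether boxes came from separate colonies. Counts were given for 33613 transcript models of 13184 loci. Names below come from the deposited identifiers alone, which name 1918 of the models, in 1918 loci. The name of a locus was given to all of its models, 4796 in total, and every other model has only a number. Models of 1 locus can share reads, and 70.8% of the models of loci with several models were at 0 in every library, against 5.53% of those of loci with 1 model. Whole loci differed too: 23.9% of loci with several models were at 0 in every library, against 5.53%. The median total count of a locus was 77 with several models and 1931 with 1. The gap was thus not only between models of a locus, and sums per locus do not settle it. Values of loci with several models, and of their separate models, are therefore uncertain. So are those of antisense pairs, because the strand setting of the counting is not stated. No identifier named the fungus.

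Total counts per library ran from 3078241 to 10314819, with a median of 4441161. In heads 7034 models passed the count filter and were tested, and in bodies 6448 were. The number of models detected, after each library was thinned to the smallest total, separated 6 libraries from the rest. These 6 had 9831 to 10393 models, and the other 31 had 7714 to 9117. They were head sham plain 02, head exposed plain 03, head exposed caffeine 04, body sham plain 01, body exposed plain 01 and body sham caffeine 01. In them, relative to the other libraries of the same group, the median model of a list was higher for antimicrobial peptides (log2 2.7 in heads, 1.52 in bodies), cytochrome P450s (1.46 and 0.63) and odorant receptors (0.87 and 0.75). It was lower for cuticle proteins (-1.02 and -0.90), the prophenoloxidase model (-1.26 and -1.34) and juvenile hormone, ecdysone and insulin signalling (-0.63 and -0.66). All counts below were therefore also made with a term for the 6 libraries and without them, both chosen after seeing the data.

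**Figure D1:**
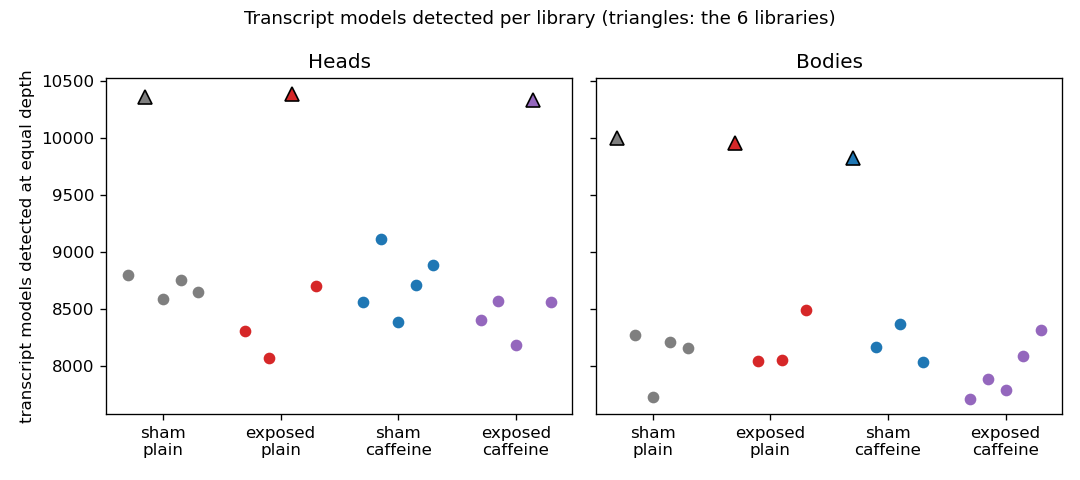
Transcript models detected per library after thinning every library to the smallest total (vertical axis, number of models), by group (horizontal axis). Triangles mark the 6 libraries with 9831 to 10393 models, and circles the other 31, with 7714 to 9117.

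Heads and bodies differed as body parts do. Odorant receptors were mostly higher in heads: 212 of the 246 tested models were higher and 10 lower, and Orco (Ffu2Orco), the coreceptor that odorant receptors need, was higher by log2 7.82 ± 0.20 (SE). The chemosensory protein CSP6 (Ffu2CSP6) was higher by 6.89 ± 0.30, SNMP1_g2 (Ffu2SNMP1_g2), a pheromone-sensing membrane protein, by 8.65 ± 0.22, and the blue opsin Blue (g05447_i1) by 5.96 ± 0.22. All 3 opsins of the eye list and 15 of 20 neuropeptides were higher in heads, with 3 neuropeptides lower. Bodies had the higher levels of 29 of 50 gut peptidases, with 10 lower, and of 5 of 6 fat body models. Chymotrypsin (g07613_i1), a digestive protease, differed by -11.66 ± 0.32, transferrin (g05065_i1), an iron-binding protein, by -7.41 ± 0.20 and the germline gene oskar (g08124_i1) by -5.65 ± 0.38. Of 31 models labelled FAS, 23 were lower in heads and 2 higher. In all, 4112 of 7858 models differed (2256 higher and 1856 lower in heads, edgeR quasi-likelihood test, adjusted p under 0.05), of which 741 were named. This fit and the list tests did not pair head and body of a box. With the box as a block the count was 3539, and 3496 of these were also called without it. As whole lists, odorant receptors (camera, adjusted p = 8.97e-30), the eye list (0.00135), neuropeptides (1.28e-05), the fat body list (0.00988), gut peptidases (7.79e-05) and FAS models (1.02e-06) stood apart from other models. With an estimated correlation the adjusted p was 0.0341 for odorant receptors, 0.0341 for the eye, 0.0359 for fat body, 0.00663 for gut peptidases, 0.104 for neuropeptides and 0.221 for FAS models. With the term for the 6 libraries all 6 lists passed (adjusted p = 1.38e-25 to 0.0165).

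The first question was which RNAs the fungus changed, taken over both foods. In heads, exposure raised several immune and stress transcripts. Spz (g14942_i1), a ligand of the Toll immune receptor, rose by log2 1.69 ± 0.24 (SE; edgeR adjusted p = 0.000963), from 15.2 ± 4.27 (SD, n = 5) to 39.0 ± 17.9 (n = 4) CPM (counts scaled to the same total in each library) on plain food and from 9.56 ± 2.02 (n = 5) to 38.7 ± 16.5 (n = 5) on caffeine food. The clip-domain serine proteases cSerineProteases g13912_i1 and g03049_i1, of the family that activates Toll and melanin formation, rose by 1.47 ± 0.22 and 0.91 ± 0.15. Lysozyme (Lys g06298_i1), which cuts bacterial cell walls, rose by 1.74 ± 0.29 and was above every sham head in 8 of 9 exposed heads. Carboxylesterase_type_B (g00997_i1), of a family that breaks down esters and many toxins, rose by 2.33 ± 0.26 (adjusted p = 0.000105) and was above every sham head in all 9 exposed heads. The odorant-binding protein OBP11S (Ffu2OBP11S) rose by 2.49 ± 0.29, the chemosensory protein CSP3 (Ffu2CSP3) by 0.82 ± 0.13 and the cuticle protein g01869_i1 by 2.74 ± 0.34. Beta-galactosidase (g03484_i1) rose by 1.62 ± 0.18, kay (g09563_i3), the Fos part of the AP-1 transcription factor, by 1.25 ± 0.23, and the heat shock model Hsps g00883_i2 by 0.93 ± 0.16. Dcg1 (g12056_i2), a basement membrane collagen, fell by 0.95 on the log2 scale (SE 0.17) and Lsd1 (g13113_i1) by 0.62 (SE 0.11). The unnamed model g05031_i1 rose by 5.97 ± 0.42 (adjusted p = 2.02e-07): all 10 sham heads were at 7.21 CPM or less and all 9 exposed heads at 54.0 or more.

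In total 83 models changed in heads, 62 up and 21 down, of which 22 were named. With transcript models summed per locus the calls of Hsps g00883_i2 (0.75, adjusted p = 0.262) and Dcg1 g12056_i2 (-0.56, 0.0743) were lost. The call of 7 further named models was lost when single libraries were left out. Cytochrome_P450 g01056_i8 (-1.90 ± 0.42) lost it without any 1 of 9 libraries, dPDK1 g09645_i3 (1.06 ± 0.23) without any 1 of 10, the peritrophin-domain model g05161_i1 (1.42 ± 0.32) and Dcg1 g12054_i1 (-0.94 ± 0.21) without any 1 of 9, and Brummer g08485_i1 (1.83 ± 0.43) and KA.2 (0.94 ± 0.22) without any 1 of 13. Cuticle protein g07154_i2 (2.20 ± 0.47) lost it without sham plain 05 (adjusted p = 0.0522), exposed plain 01 (0.0560) or exposed plain 02 (0.0774). The count was 55 without exposed plain 02, 157 without exposed plain 03 and 125 without exposed caffeine 04. It was 700 (417 up, 283 down) with the term for the 6 libraries and 790 without them, and all 83 models kept their call and sign with the term. DESeq2 gave 211 and limma voom with quality weights 1268.

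By list, clip-domain proteases and serpins were higher in exposed heads than other models (camera, adjusted p = 0.0264; 2 of 14 models of 9 loci up, 3 when adjusted over the list alone), as were antimicrobial peptides (0.0264; 0 of 4, 1 over the list alone), heat shock proteins (0.0264; 1 of 30, 1) and peritrophin-domain chitin-binding proteins (0.00103; 1 of 19 up, 4 up and 1 down over the list alone). Odorant receptors were lower, with a median of -0.27 (5.68e-08; 0 of 243 at an adjusted p under 0.05, also over the list alone), as were cytochrome P450s (0.00934; 1 of 39 down, 3 down and 1 up over the list alone) and vitellogenins (0.0491; 0 of 4, also over the list alone), which carry yolk lipid. With an estimated correlation none of these held: the adjusted p was 0.151 for clip-domain proteases, for antimicrobial peptides and for peritrophins, 0.338 for heat shock proteins and for vitellogenins, 0.549 for odorant receptors and 0.740 for cytochrome P450s. Of these lists, antimicrobial peptides, cytochrome P450s, odorant receptors, heat shock proteins (0.45 in heads and 0.45 in bodies) and clip-domain proteases (0.21 and 0.39) were also higher in the 6 libraries, and peritrophins lower (-0.59 and -0.40). With a term for the 6, 8 odorant receptors and 8 P450s were lower and 1 P450 higher, and the adjusted p was 0.185 for antimicrobial peptides, clip-domain proteases, heat shock proteins and vitellogenins. Toll, IMD and JAK/STAT signalling did not pass as a list (0.139; 1 of 22 up, 2 up and 1 down over the list alone). Neither did immune recognition, lysozymes and chitinases, glutathione S-transferases and carboxylesterases, gustatory and aminergic receptors, desaturases and elongases, FAS models, cuticle proteins, odorant-binding, chemosensory and NPC2 proteins, juvenile hormone, ecdysone and insulin signalling, neuropeptides, the eye list, the fat body list, gut peptidases, the germline list or MRJP (adjusted p = 0.228 to 0.965). The prophenoloxidase model PPO g06735_i1, whose enzyme makes melanin, had 0.21 ± 0.28 (adjusted p = 0.926), Knottin-like_peptide g01168_i1 2.27 ± 0.57 (0.0647), the defensin model def g13760_i1 2.68 ± 1.27 (0.540), def g13760_i2 1.58 ± 0.88 (0.648) and def g14347_i1 0.67 ± 0.32 (0.551). The vitellogenin models had -1.14 ± 0.58 for g07907_i1 (0.589), -0.71 ± 0.56 for g10472_i1 (0.823), -0.68 ± 0.47 for g02204_i1 (0.784) and -0.25 ± 0.18 for g02525_i1 (0.813).

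In bodies, exposure raised an overlapping set. Spz rose by 1.76 ± 0.24 (adjusted p = 0.000367), and in all 9 exposed bodies it was above every sham body, as were cSerineProteases g03049_i1 (1.71 ± 0.24), Carboxylesterase_type_B (2.42 ± 0.41, with no adjusted p from DESeq2) and dPDK1 g09645_i3 (2.08 ± 0.24, adjusted p = 9.68e-05), named after a kinase of insulin signalling. Serine protease g13912_i1 rose by 1.18 ± 0.24, OBP11S by 2.06 ± 0.41 and OBP6 (Ffu2OBP6) by 1.41 ± 0.30. OBP3 (Ffu2OBP3) rose by 2.53 ± 0.35 (adjusted p = 0.000448), from 5.83 ± 4.22 (SD, n = 5) to 29.9 ± 12.6 (n = 4) CPM on plain food and from 3.72 ± 1.34 (n = 4) to 24.2 ± 10.0 (n = 5) on caffeine food. Kay rose by 1.14 ± 0.21, Peptidase_C12 g04501_i3, a ubiquitin hydrolase, by 1.40 ± 0.19 and Peptidase_M2 g12553_i1 by 0.91 ± 0.19. Transferrin g00660_i1 rose by 1.46 ± 0.31, and all transferrin models together held 2.63% ± 0.642 (SD, n = 4) of counts in exposed bodies on plain food, against 0.766% ± 0.380 (n = 5) in sham bodies, and on caffeine food 2.63% ± 0.641 (n = 5) against 1.21% ± 0.446 (n = 4). The call of g00660_i1 was lost without sham caffeine 03 (adjusted p = 0.0527). In heads transferrin models held 1.46% ± 0.252 (SD, n = 4) in exposed and 0.66% ± 0.391 (n = 5) in sham ants on plain food. On caffeine food they held 1.42% ± 0.335 (n = 5) and 0.752% ± 0.099 (n = 5). Model g00660_i1 was above every sham head in 7 of 9 exposed heads. It was not called in heads in the main fit, but was with the term for the 6 libraries. Orco, low in bodies, rose by 1.51 ± 0.32 (adjusted p = 0.0166), and this call was lost without exposed plain 05 (adjusted p = 0.0557) or sham caffeine 04 (0.0518) and with no count filter. Among cytochrome P450s, enzymes that oxidise hormones, fats and toxins, g10222_i1 fell by 0.88 (SE 0.18) and g14703_i1 by 0.84 (SE 0.17). The unnamed model g05031_i1 rose by 6.90 ± 0.48 (adjusted p = 1.04e-07), from at most 11.5 CPM in the 9 sham bodies to at least 219 in the 9 exposed ones.

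**Figure D2:**
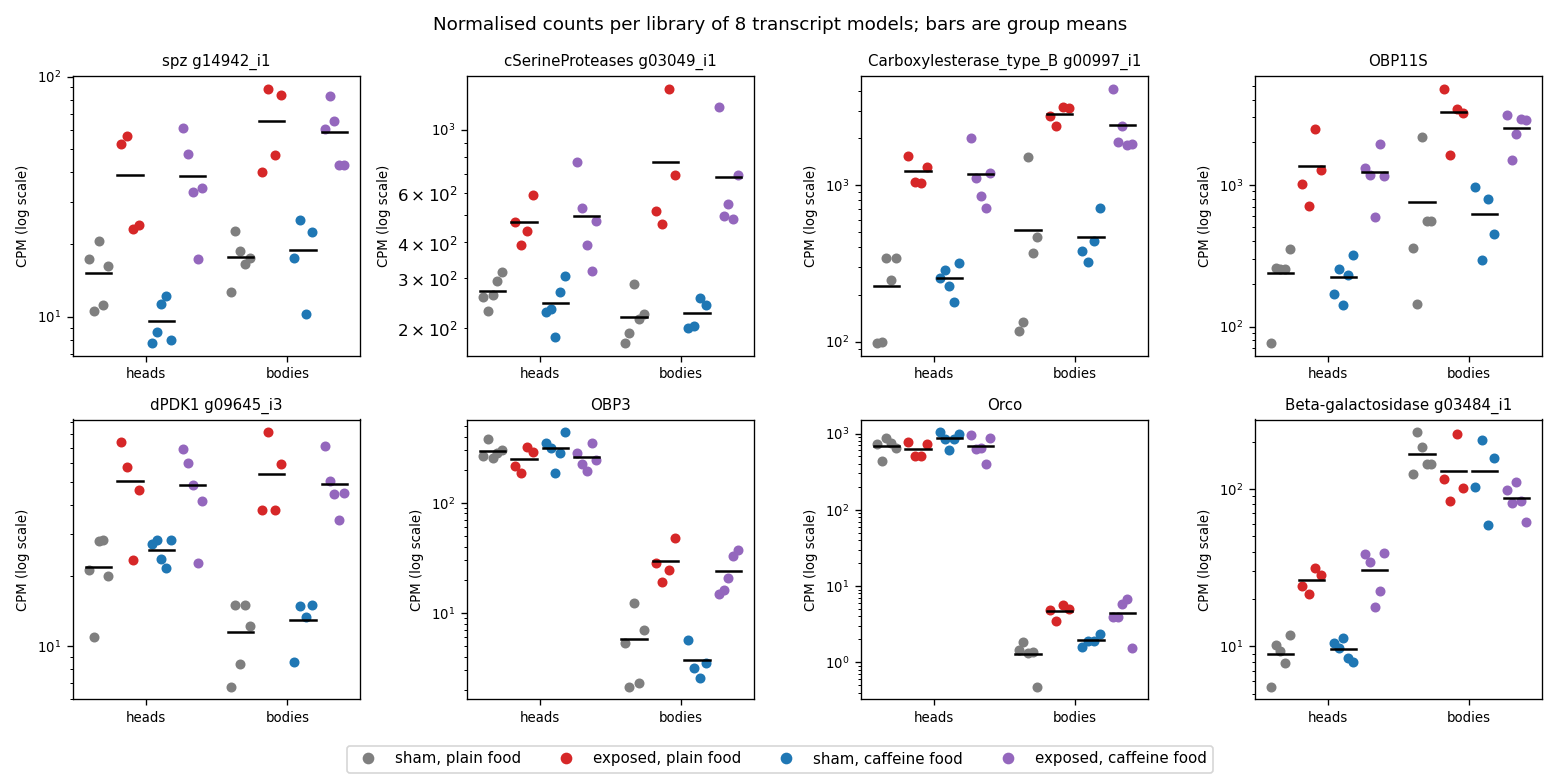
Level of 8 transcript models in each library (vertical axis, CPM on a log scale) by group (horizontal axis). Points are libraries and bars are group means. Carboxylesterase_type_B and cSerineProteases g03049_i1 were above every sham library in all 9 exposed libraries of either body part.

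The total in bodies was 148 models, 104 up and 44 down, of which 28 were named (22 up, 6 down). Chance was not excluded for this count: 7 of 100 splits of the libraries, the real one included, called as many, and the highest other called 1266. With the term for the 6 libraries only the real split, 1 of 100, called as many as it did. The calls of 13 of the named ones were lost without any 1 of 8 to 16 of the 18 libraries: Knottin-like_peptide g01168_i1 (2.11 ± 0.55), P450s g02380_i1 (-0.88 ± 0.23) and g10224_i1 (-0.66 ± 0.16), Elongases g02565_i2 (0.85 ± 0.20), cuticle protein g01869_i1 (1.5 ± 0.38), chymotrypsins g11317_i1 (-1.44 ± 0.33) and g07612_i1 (1.19 ± 0.28), the fat lipase Brummer (1.61 ± 0.41), IR111 (1.56 ± 0.37), acyl_carrier_protein_domain g08615_i1 (1.52 ± 0.38), Jra g12377_i1, the Jun part of AP-1 (1.17 ± 0.30), Peptidase_M2 g00412_i2 (0.96 ± 0.23) and Dcg1 g12056_i2 (-0.75 ± 0.19). The count was 235 without body sham plain 03, 97 without sham plain 04, 67 and 68 without exposed plain 02 and 05, 83, 89, 79 and 94 without sham caffeine 01, 03, 04 and 05, and 81, 88 and 86 without exposed caffeine 01, 02 and 03. With the term for the 6 libraries it was 275 (169 up, 106 down), including all 148, and 105 without them. With the term and without body sham plain 03 it was 572. DESeq2 gave 294 and limma voom 843, and with no count filter it was 97.

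As lists in bodies, cytochrome P450s were lower after exposure, with a median of -0.76 (camera, adjusted p = 2.52e-06; 4 of 32 down, 8 over the list alone), and vitellogenins were lower, with a median of -1.17 (0.0232; 0 of 4, 3 down over the list alone). Immune recognition was higher, with a median of 0.76 (0.0240; 0 of 5, also over the list alone). For all 3 the adjusted p was 0.346 with an estimated correlation, and with a term for the 6 libraries, in which P450s were higher, it was 1.22e-05 for P450s (8 of 32 down), 0.0613 for vitellogenins and 0.0620 for immune recognition. Vitellogenin g07907_i1 had -1.48 ± 0.53 (0.197), with 77362 ± 40979 (SD, n = 5) CPM in sham and 21273 ± 22167 (n = 4) in exposed bodies on plain food, and 71394 ± 16915 (n = 4) and 33249 ± 22466 (n = 5) on caffeine food. The sham bodies on plain food include body sham plain 03, at 5727 against 88235 to 109954 in the other 4. Models g02204_i1, g10472_i1 and g02525_i1 had -1.94 ± 0.66 (0.165), -0.86 ± 0.30 (0.195) and -0.27 ± 0.20 (0.587). PPO had 0.67 ± 0.30 (0.362), def g13760_i1 -1.19 ± 0.91 (0.6), def g13760_i2 -0.65 ± 0.69 (0.684) and def g14347_i1 0.72 ± 0.43 (0.512). Antimicrobial peptides, Toll signalling, clip-domain proteases, lysozymes, glutathione S-transferases and carboxylesterases, heat shock proteins, the receptor and odorant-binding lists, desaturases, FAS models, cuticle proteins, the hormone list, neuropeptides, fat body, gut peptidases, peritrophins, germline and MRJP did not pass as lists (adjusted p = 0.0657 to 0.888), and prophenoloxidase and eye had too few members.

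Each food was also taken alone, since the study compares the response to the fungus with and without caffeine. In heads 14 models changed on plain food (13 up, 1 down) and 19 on caffeine food (15 up, 4 down), and 11 were called on both, where 0.0378 would be by chance. In bodies the counts were 25 (all up) and 13 (11 up, 2 down), with 10 on both and 0.0504 by chance. The foods share no library. Every model called on 1 food had the same sign on the other in that body part. With the term for the 6 libraries this held in heads for 154 of 155 called on plain food and 116 of 124 on caffeine food, and in bodies for 93 of 94 and 23 of 23. Carboxylesterase_type_B rose in heads by 2.45 ± 0.37 on plain and 2.21 ± 0.36 on caffeine food (adjusted p = 0.0105 and 0.0101), and g05031_i1 by 6.04 ± 0.60 and 5.91 ± 0.58. In bodies g05031_i1 rose by 7.15 ± 0.64 and 6.66 ± 0.69, and dPDK1 by 2.24 ± 0.34 and 1.92 ± 0.35 (adjusted p = 0.00435 and 0.0194), the latter call being lost without any 1 of 5 libraries and with no count filter. In a fit of only the groups compared, the calls on plain food of Carboxylesterase_type_B in heads (adjusted p = 0.220) and dPDK1 in bodies (0.0858) were lost.

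The counts for single foods moved when single libraries were left out. In heads on plain food the count was 7 without sham plain 04, 4, 6 and 27 without exposed plain 01, 02 and 03, and on caffeine food 6, 8, 9, 9 and 7 without sham caffeine 01 to 05 and 9 and 6 without exposed caffeine 01 and 02. In bodies on plain food it was 51 and 13 without sham plain 03 and 04 and 15 without exposed plain 05, and on caffeine food 3, 1, 1 and 2 without sham caffeine 01, 03, 04 and 05 and 1 and 8 without exposed caffeine 01 and 03. The term for the 6 libraries gave 155 and 124 models in heads and 94 and 23 in bodies, and leaving the 6 out gave 131 and 130 in heads and 18 and 15 in bodies. DESeq2 gave 74 and 73 in heads and 103 and 67 in bodies, limma voom 368 and 240, and 548 and 128. A fit of only the groups compared gave 1 and 16 in heads and 6 and 18 in bodies.

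Between body parts, 6137 models were tested in both. Of 60 raised in heads and 102 raised in bodies, 38 were the same, against 0.997 by chance, and of 21 and 40 lowered, 4 were the same, against 0.137. Heads and bodies came largely from the same boxes, so these counts are not independent. The named models raised in both were spz, both serine proteases, Carboxylesterase_type_B, OBP11S, dPDK1, kay, Peptidase_C12, Peptidase_M2 g12553_i1, Brummer and cuticle protein g01869_i1, and Dcg1 g12056_i2 was lowered in both. Of these calls, Brummer in both parts, dPDK1 in heads, and cuticle protein g01869_i1 and Dcg1 g12056_i2 in bodies were lost when single libraries were left out. Dcg1 g12056_i2 in heads was lost with sums per locus.

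**Figure D3:**
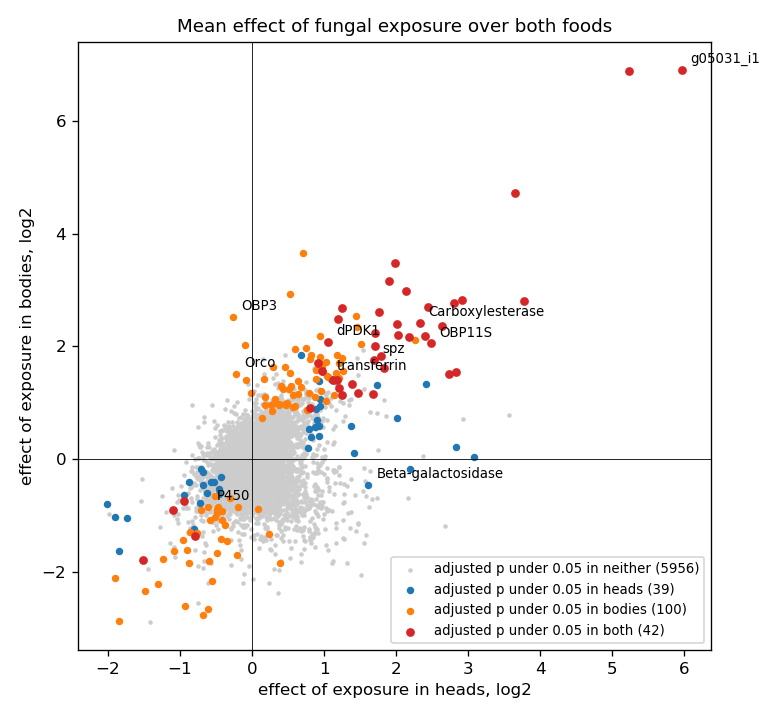
Mean effect of exposure over both foods in heads (horizontal axis, log2) and bodies (vertical axis, log2) for the 6137 transcript models tested in both. Colours mark the 39 models called in heads only, the 100 called in bodies only, the 42 called in both and all others.

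A direct test of the difference between body parts called 5 models. OBP3 and Orco rose in bodies and not in heads: the effect in heads minus that in bodies was -2.82 ± 0.36 for OBP3 (adjusted p = 4.38e-05) and -1.76 ± 0.31 for Orco (0.00593). In heads OBP3 was at 298 ± 50.5 (SD, n = 5) CPM in sham and 253 ± 63.2 (n = 4) in exposed ants on plain food, and at 315 ± 91.9 (n = 5) and 258 ± 60.3 (n = 5) on caffeine food. Beta-galactosidase rose in heads and not in bodies, with a difference of 2.06 ± 0.31 (0.000541), and its levels in bodies were 166 ± 41.9 (n = 5) in sham and 131 ± 62.5 (n = 4) in exposed ants on plain food, and 130 ± 63.1 (n = 4) and 87.7 ± 18.6 (n = 5) on caffeine food. The unnamed models g12416_i2 (2.62 ± 0.45) and g11435_i1 (-2.94 ± 0.53) made up the rest. Blocked by box, which pairs head and body of the same ants, the count was 3 and the adjusted p was 0.00720 for OBP3, 0.0337 for Beta-galactosidase, 0.00720 for g11435_i1, 0.670 for Orco and 0.538 for g12416_i2. The differences of the last 2 were -1.77 ± 0.42 and 2.60 ± 0.59, so their folds stayed and their SE grew. The count was 10 without head sham plain 02 and 8 without body sham plain 03, 13 with the term for the 6 libraries, 11 without them, 14 with DESeq2 and 36 with limma voom. Odorant receptors passed as a list (camera, adjusted p = 0.00481, 0.871 with an estimated correlation), with a direction of the test (lower) that differed from the sign of their median (0.10) and mean (0.17); with the term the median was -0.21 (4.24e-07, 0.427 with an estimated correlation).

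Caffeine itself changed 1 model in heads of sham ants, the unnamed g07155_i1. It rose by 3.58 ± 0.57 (edgeR, adjusted p = 0.0404, 1.35e-08 to 0.201 over all alternatives), from 35.7 ± 21.7 (SD, n = 5) to 428 ± 98.9 (n = 5) CPM, and every caffeine-fed sham head was above every plain-fed one. In exposed heads it was at 35.2 ± 21.4 (n = 4) on plain and 39.6 ± 26.1 (n = 5) on caffeine food, and among the effects of exposure on caffeine food it fell by 3.43 (SE 0.56, adjusted p = 0.0101), lost without exposed caffeine 02 (adjusted p = 0.0521). The caffeine call was lost without any 1 of the 10 libraries compared, with the replicate block and without the 6 libraries, and kept with the term for the 6. No P450 and no gustatory or aminergic receptor was called for caffeine in either body part.

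Elsewhere edgeR called 0 models for caffeine. The numbers at an unadjusted p under 0.05 were 219 in sham heads (1 called), 43 in exposed heads, 120 in sham bodies, 107 in exposed bodies, and for the mean over both exposures 107 in heads and 142 in bodies. DESeq2 called 13 in sham heads, 0 in exposed heads, 0 in sham and 0 in exposed bodies, and 1 for the mean in heads and 1 in bodies. Limma voom called 3 in sham heads and 0 in the others, and the term for the 6 libraries gave the same numbers as limma voom. For the difference of the caffeine effect between body parts edgeR called 0 (182 at an unadjusted p under 0.05), DESeq2 2 and limma voom 0, and edgeR 1 without body sham plain 03. In simulated data of the same depth and spread, 4-fold changes were recovered in 74.0% of models for caffeine in sham heads, 59.2% in exposed heads, 42.0% in sham bodies and 49.5% in exposed bodies, and 2-fold changes in 28.9%, 15.5%, 6.12% and 0%. The simulated data held no structure among the libraries. The 95% intervals of the mean caffeine effect excluded a 4-fold change in either direction for 94.2% of models in heads and 93.8% in bodies.

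Some lists shifted with caffeine without single calls. In bodies, over both exposures, P450s were lower, with a median of -0.35 (camera, adjusted p = 3.89e-05; 0.339 with an estimated correlation), gut peptidases lower, with -0.29 (0.0465; 0.179), and vitellogenins higher, with 0.32 (0.0315; 0.339). In exposed bodies the medians were -0.51 for P450s (7.81e-05; 0.378), 0.82 for vitellogenins (0.0160; 0.279) and 0.26 for cuticle proteins (0.0210; 0.534), in each case with the second p from an estimated correlation. In exposed heads vitellogenins had a median of 0.77 (0.0291; 0.468), odorant receptors -0.20 (0.00555; 0.783), the juvenile hormone, ecdysone and insulin list -0.17 (0.00944; 0.468) and neuropeptides -0.13 (0.0250; 0.762). In these lists 0 models passed an adjusted p under 0.05 over all models or over the list alone. P450s and odorant receptors were higher and cuticle proteins, neuropeptides and the hormone list lower in the 6 libraries, none of which was a caffeine-fed exposed body or a caffeine-fed sham head. With the term for the 6, over both exposures in bodies P450s (adjusted p = 0.00286) and vitellogenins (0.0159) passed and gut peptidases (0.0664) did not, and in exposed bodies P450s (0.0132) and vitellogenins (0.00430) passed and cuticle proteins (0.485) did not. In exposed heads the hormone list (0.0137) and neuropeptides (0.0137) passed with it, and vitellogenins (0.172) and odorant receptors (0.172) did not.

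Whether caffeine changed the response to the fungus was tested as the interaction. The list of juvenile hormone, ecdysone and insulin signalling stood out in heads: its 27 models, of 21 loci, had a median interaction of -0.48 (camera, adjusted p = 4.01e-08; 0.0313 with an estimated correlation). In sham heads these models were higher on caffeine food, with a median of 0.34 (1.76e-05; 0.132 with an estimated correlation), and 4 of them passed when adjusted over the list alone, against 0 over all models tested. The insulin receptor models dINR g12500_i1 and g06436_i1 had 1.17 ± 0.28 and 1.04 ± 0.27, and Kr-h1 g07696_i1 and g07696_i2, a transcription factor induced by juvenile hormone, 1.87 ± 0.48 and 1.69 ± 0.51. The levels of dINR g12500_i1 were 46.4 ± 12.6 (SD, n = 5) in sham plain, 45.6 ± 13 (n = 4) in exposed plain, 105 ± 27.1 (n = 5) in sham caffeine and 41.2 ± 13 (n = 5) CPM in exposed caffeine heads. Kr-h1 g07696_i1 was at 14.0 ± 6.66, 20.5 ± 9.84, 51.2 ± 26.3 and 17.2 ± 8.71 in the same order. For dINR g12500_i1, dINR g06436_i1 and Kr-h1 g07696_i1, all 5 caffeine-fed sham heads were above every other head. On caffeine food, exposure lowered the list, with a median of -0.31 (5.72e-05; 0.109 with an estimated correlation). There dINR g12500_i1 fell by 1.35 (SE 0.28, adjusted p = 0.0477), a call lost without any 1 of the 10 libraries compared, and 3 models were lower over the list alone.

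**Figure D4:**
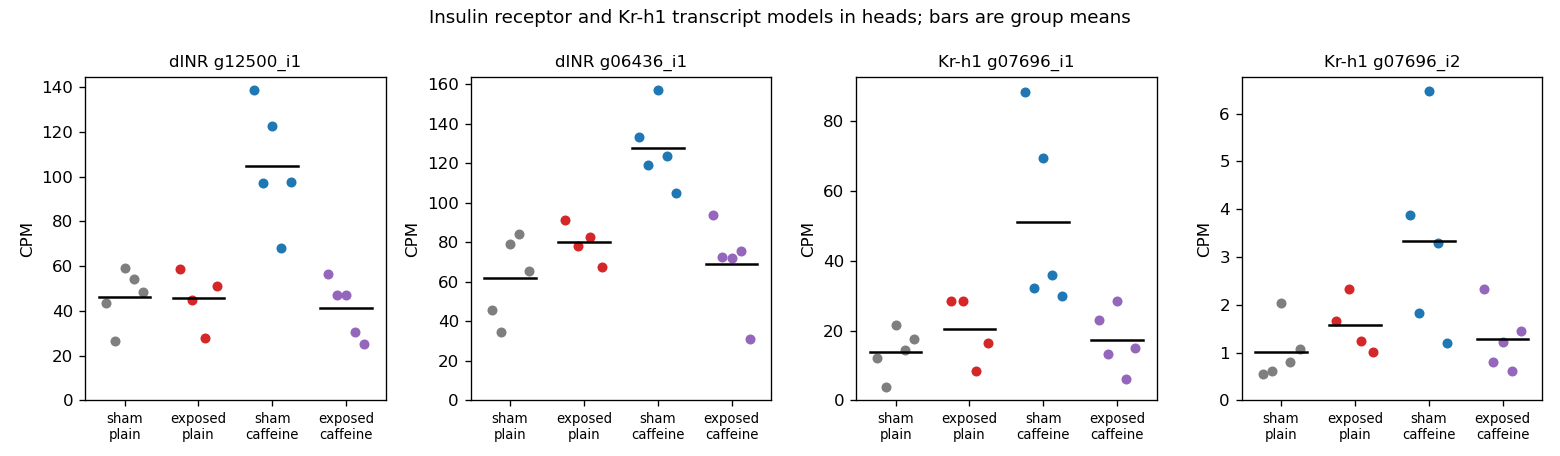
Level of 4 transcript models of insulin receptors (dINR) and Kr-h1 in heads (vertical axis, CPM, from 0) by group (horizontal axis). Points are libraries and bars are group means. For dINR g12500_i1 the mean was 105 in caffeine-fed sham heads and 41.2 to 46.4 in the other groups.

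The hormone list was lower in the 6 libraries, and none of these was a caffeine-fed sham head. With a term for them its median interaction in heads was -0.29 (adjusted p = 5.69e-08; 0.0409 with an estimated correlation). Fry, which asks whether the models of a list move 1 way, gave an adjusted p of 0.140. In bodies the list did not pass (median -0.05, adjusted p = 0.693). Other lists that passed for the interaction were neuropeptides in heads (median -0.21, adjusted p = 0.0413; 0.848 with an estimated correlation and 0.169 with the term) and, in bodies, FAS models (-0.66, 0.0254; 0.814) and cuticle proteins (0.46, 0.00294; 0.752). In the 3 body libraries among the 6, none of them caffeine-fed and exposed, FAS models were higher by 0.97 and cuticle proteins lower, at -0.90, and with the term neither list passed (-0.18, adjusted p = 0.549, and 0.21, 0.279). For single models edgeR called 0 interactions in either body part, with 82 in heads and 68 in bodies at an unadjusted p under 0.05. DESeq2 called 2 in heads and 0 in bodies, and limma voom 0 in both. With the term for the 6 libraries edgeR also called 0 in both. In simulated data a 4-fold interaction was recovered in 25% of models in heads and 2.02% in bodies, and a 2-fold one in 1.01% and 0%. With the term 4-fold interactions were recovered in 71.7% and 34.3%, and 2-fold ones in 30.9% and 3%. Neither simulation held structure among the libraries.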

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

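The tests of the 6 libraries, of body sham plain 03 and of OBP3 and Orco with the term for the 6 were chosen only after the result was seen, as was the reading of the head RNA test for Orco, while that test for OBP3 was chosen before.

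The 6 libraries with more models detected had 10361 in head sham plain 02 (others of its group 8592 to 8797), 10335 in head exposed caffeine 04 (8190 to 8569) and 10007 in body sham plain 01 (7730 to 8271), with head exposed plain 03, body exposed plain 01 and body sham caffeine 01 also above the gap. A state of the ants of a box would put head and body of that box on the same side, but 0 of the boxes had both among the 6, which argues against it. RNA of the other body part would shift heads and bodies in opposite directions, while the shifts correlated at 0.954 over the 3872 models with at least 10 counts in every library, which argues against it too. A difference in library preparation or RNA handling stays open: the value of 0.954 goes with any source shared by heads and bodies, and the labels give 1 protocol for all and do not name the extracts that were cleaned. The common biological coefficient of variation went from 0.49 to 0.27 in heads and from 0.53 to 0.39 in bodies once the 6 had a term of their own, so counts are given with that term as well.

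Body sham plain 03 was far from the other sham bodies on plain food. It had 1509 CPM of Carboxylesterase_type_B (others 116 to 466.1), 2189 of OBP11S (144 to 559), 111 of lysozyme Lys g06298_i1 (8.57 to 15.5) and 5727 of vitellogenin g07907_i1 (88235 to 109954), and vitellogenins held 0.711% of its counts (9.24 to 11.3). Head RNA in the pool may be set aside, since the deviation correlated at -0.238 with the difference of heads from bodies. A wrong label would put it at 1 on a scale from sham (0) to exposed (1) over 13 models called on caffeine food, and it was at 0.209, with the other sham bodies at -0.112 to 0.0767 and exposed bodies at 0.741 to 1.13, while g05031_i1 was at 4.70 CPM against at least 219 in exposed bodies. A state of the ants of its box could not be told apart, as the correlation with the head library of that box was 0.0472, within the range of the other heads (-0.198 to 0.267), though vitellogenins were low in that head library too (0.465% against 5.89 to 10.0).

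OBP3 and Orco rose in exposed bodies and not in heads, with tissue differences of -2.82 and -1.76. Head RNA in the body pools of exposed ants could give this, and 20 other models at least 32-fold higher in heads had a median effect of -0.18 (quartiles -0.70 to 0.19, median SE 0.42), with 1 called up. The 1 called up was OBP6 (1.41 ± 0.30, edgeR adjusted p = 0.0166), another odorant-binding protein. For OBP3, whose rise was 8.55% of the head level, such a share would raise a 32-fold model by log2 1.90, so the values argue against it, but for Orco the rise was 0.446% and the expected 0.19 is under the SE, so head RNA stays open for Orco. The 6 libraries are not the source either, since with a term for them Orco rose by 1.51. With a block per box the difference was -2.76 ± 0.39 (SE) for OBP3 (adjusted p = 0.00720, 2.62e-11 to 0.00720 over all alternatives) and -1.77 ± 0.42 for Orco (0.670, 0.000247 to 0.670), whose call ended with a wider SE (0.31 without the block) and an unchanged fold.

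The other tissue differences were 2.06 for Beta-galactosidase g03484_i1, 2.62 for the unnamed g12416_i2 and -2.94 for the unnamed g11435_i1. Chance was not excluded for the count of 5: 3 of 60 splits of the libraries, the real one included, called as many, and the highest other split called 1910, which points to a structure among the libraries. The call of OBP3 was kept in every alternative (adjusted p at most 0.00720).

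The median interaction of the juvenile hormone, ecdysone and insulin list in heads was -0.48. Summed over its 21 loci it was -0.51 (camera p = 8.12e-08 over all loci, 0.00382 with an estimated correlation, edgeR fit).

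Single values outside their groups were lysozyme Lys g06298_i1 at 32.5 CPM in head exposed plain 03 (others 9.06 to 12.9), which is 1 of the 6 libraries. Model g07155_i1 was at 67.2 CPM in head exposed plain 01 (23.4 to 25.2). In body exposed caffeine 01, Carboxylesterase_type_B was at 4139 CPM (1800 to 2394) and cSerineProteases g03049_i1 at 1199 (483 to 690). Head sham caffeine 02 had 10314800 counts (others 4510643 to 5314390). In all, 13 of 144 groups of values held such a value, where the rule picks 5% by chance.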

How the results depend on the processing

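The term for the 6 libraries, leaving them out, the term without body sham plain 03 and the sums per locus were chosen after seeing the data, and the other settings before. None of the 199 named calls reversed sign in any setting, and every model called was also called, with the same sign, when the term was added.

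DESeq2 called more models: in heads 74 on plain food, 73 on caffeine food, 13 for caffeine in sham ants, 2 for the interaction, 211 for the mean pathogen effect and 1 for mean caffeine, and in bodies 103, 67, 294 for the mean pathogen effect and 1 for mean caffeine. For the tissue difference it called 14 for the pathogen and 2 for caffeine. Limma voom with quality weights called 368 on plain food, 240 on caffeine food, 3 for caffeine in sham ants and 1268 for the mean in heads, 548, 128 and 843 in bodies, and 36 for the tissue difference in the pathogen effect.

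With no filter bodies had 8 models on caffeine food and 97 for the mean pathogen effect. With RLE factors or the filter at 1 CPM no count moved by over 1.5 times, and the mean pathogen effect had 86 and 89 models in heads and 135 and 118 in bodies. With only the 2 groups compared in the fit, heads had 1 on plain food and 3 for caffeine in sham ants, and bodies 6 on plain food.

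With the replicate block heads had 8 models on plain food, 9 on caffeine food and 0 for caffeine in sham ants, bodies had 38 on plain food, and the tissue difference had 3. The mean pathogen effect had 58 models in heads and 167 in bodies. Within a body part the labels give libraries of the same number only that number in common. Their mean correlation was 0.0458 in heads and 0.215 in bodies. All 3 body libraries among the 6 have the number 01, and with the shift of the 6 taken out the mean was 0.00958 in bodies and 0.102 in heads. Between libraries of other numbers it was then -0.00605 in bodies and -0.0238 in heads. In bodies 7 of 18 libraries, and in heads 12 of 19, correlated best with a library of their own number. For heads the cause was not tested.

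With the library-set term heads had 155 models on plain food, 124 on caffeine food, 3 for caffeine in sham ants and 700 for the mean pathogen effect. Bodies had 94, 23 and 275, and the tissue difference 13. Without the 6 libraries heads had 131, 130, 0 for caffeine in sham ants and 790, bodies had 18, 15 and 105, and the tissue difference 11. With the term and without body sham plain 03, bodies had 263 on plain food, 76 on caffeine food and 572 for the mean, and the tissue difference 26 for the pathogen and 1 for caffeine. Summed per locus, heads had 14, 19 and 78 and bodies 23, 12 and 136.

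Leaving out 1 library gave 4 to 27 models in heads on plain food (7 without sham plain 04, 4, 6 and 27 without exposed plain 01, 02 and 03) and 6 to 28 on caffeine food (6, 8, 9, 9 and 7 without sham caffeine 01 to 05, 9 and 6 without exposed caffeine 01 and 02). The single caffeine call was lost, leaving 0, without any of the 10 libraries compared. The mean pathogen effect in heads had 55 without exposed plain 02, 157 without exposed plain 03 and 125 without exposed caffeine 04. In bodies, plain food had 51 and 13 without sham plain 03 and 04 and 15 without exposed plain 05, and caffeine food 3, 1, 1 and 2 without sham caffeine 01, 03, 04 and 05 and 1 and 8 without exposed caffeine 01 and 03. The mean had 235 and 97 without sham plain 03 and 04, 67 and 68 without exposed plain 02 and 05, 83, 89, 79 and 94 without sham caffeine 01, 03, 04 and 05, and 81, 88 and 86 without exposed caffeine 01, 02 and 03. The tissue difference for the pathogen had 10 without head sham plain 02 and 8 without body sham plain 03, and that for caffeine 1 without body sham plain 03.

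Of 199 named calls, 18 of the 36 for single comparisons of groups held with only the 2 groups compared, and 165 held with the block, 171 with no filter, 195 with DESeq2, 199 with the term and 185 of 197 without the 6. Over single libraries left out, 4864 of 5286 held. For the interaction, with a count of 0 in both fits, 25% of 4-fold changes in simulated models were recovered in heads and 2.02% in bodies without the term, and 71.7% and 34.3% with it.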

Other observations

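The test of food dependence and the splits of libraries were written before the result was seen, and their repeats with the library-set term were chosen only after it.

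In heads, exposure on caffeine food raised cuticle protein g01869_i1 by 3.08 ± 0.49 and spz by 2.02 ± 0.34, the latter call being lost without any 1 of 4 libraries and with the replicate block. In bodies on plain food spz rose by 1.88 ± 0.33 and cSerineProteases g03049_i1 by 1.81 ± 0.33, each lost without either of 2 libraries and in a fit of only the 2 groups compared. PPO and the defensins passed for exposure in neither body part, while spz and the clip-domain protease models g03049_i1 and g13912_i1 passed in both. In exposed bodies on plain food the vitellogenins together held 2.59% ± 2.69 (SD, n = 4) of counts against 8.50% ± 4.42 (n = 5) in sham bodies (0.711 in body sham plain 03, 9.24 to 11.3 in the other 4), and on caffeine food 3.71% ± 2.50 (n = 5) against 7.93% ± 2.21 (n = 4).

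On single foods, lists of exposed heads that passed on plain food were P450s (median -0.24, adjusted p = 0.00327; 0.667 with an estimated correlation), vitellogenins (-1.27, 0.0149; 0.312), odorant receptors (-0.15, 0.00646; 0.804) and peritrophins (0.26, 0.0178; 0.354). On caffeine food they were clip-domain proteases (0.47, 0.00322; 0.109), heat shock proteins (0.22, 0.00824; 0.2), odorant receptors (-0.33, 1.59e-09; 0.561) and peritrophins (0.31, 0.00183; 0.147). In bodies on plain food they were immune recognition (0.21, 0.0415; 0.438), P450s (-0.51, 0.00116; 0.474) and vitellogenins (-1.64, 0.0122; 0.354), and on caffeine food P450s (-0.86, 1.37e-06; 0.708), FAS models (-0.76, 0.00470; 0.708) and odorant receptors (-0.53, 0.0363; 0.708). With the term for the 6 libraries the lists that no longer passed were vitellogenins (adjusted p = 0.0887) and peritrophins (0.0777) in heads on plain food, clip-domain proteases (0.0585) and heat shock proteins (0.0965) in heads on caffeine food, immune recognition (0.0915) in bodies on plain food, and FAS models (0.0840) and odorant receptors (0.204) in bodies on caffeine food.

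Caffeine might change the size of the response to the fungus, but over the 83 models called in heads, the mean effect in the direction of the call was 1.44 on plain and 1.41 on caffeine food, a difference of -0.0358 (permuted -0.47 to 0.48, permutation p = 0.883). Over the 148 called in bodies it was 1.68 and 1.47, a difference of -0.20 (permuted -0.48 to 0.51, permutation p = 0.456). With the shift of the 6 libraries taken out the differences were 0.02 and -0.32 (permutation p = 0.943 and 0.169). Both values met the bar for no dependence set before (within the permuted range and within 0.5 of 0), but this was made stricter after they were seen, by adding the permuted range to the value, since that range alone is about as wide as the bar. A change near 0.5 therefore stays open in both as deposited, and in heads the stricter bar was met only with the shift of the 6 taken out (permuted -0.41 to 0.42). The models were picked from the same data for their mean effect over both foods, which favours those that respond alike on either. Differences of opposite sign also cancel in the mean over models. The test thus covers only the average response of these models, not whether caffeine changed the response of single or other models.

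Splits of the libraries into other groups of the same sizes, the real split counted as 1 of 100, showed whether chance can be excluded. In heads it can be for plain food (1 of 100 as large; real 14, highest other 1), caffeine food (1; 19 and 0) and the mean pathogen effect (1; 83 and 8), and with the term for plain food (1; 155 and 137), caffeine food (1; 124 and 0) and the mean (1; 700 and 597). For caffeine in sham heads (1; 1 and 0) a count of 1 decides little, since it was 0 without any 1 of the 10 libraries compared, with the replicate block and without the 6 libraries. In bodies the bar was met for caffeine food (1, with 13 and 3) and plain food (2, with 25 and 391). With the term it was met for plain food (1, with 94 and 5), caffeine food (2, with 23 and 34) and the mean (1, with 275 and 0). For the mean pathogen effect in bodies without the term it was not met (7 of 100, with 148 and 1266). Meeting the bar does not exclude chance, since 100 splits cannot show a share under 1 of 100. For plain food in bodies, and for caffeine food in bodies with the term, another split also called more models than the real one. Head against body stood out (1 of 60; 4112 and 2533), and the tissue difference for the pathogen did not (3 of 60; 5 and 1910). Where the real count was 0, all splits were as large: 100 of 100 for caffeine in exposed heads (highest other 2190), interaction in heads (2828), mean caffeine in heads (787), caffeine in sham bodies (773) and in exposed bodies (0), interaction in bodies (1198) and mean caffeine in bodies (1328), and 60 of 60 for the tissue difference in caffeine (1211). Splits with many times the real count point to a structure among the libraries. Without the term, the highest splits for plain food in bodies (391), caffeine in sham bodies (773) and caffeine in exposed heads (2190) were uneven in the 6 libraries. In each the 2 groups differed by 2 of them. The term for the 6 libraries lowered the highest other split in bodies for the mean (1266 to 0) and plain food (391 to 5). It raised it for caffeine food in bodies (3 to 34) and in heads for the mean (8 to 597) and plain food (1 to 137, with a difference of 0). In each of these comparisons other splits that also differed by 2 called 0 models, so an uneven share of the 6 does not by itself give many calls. How the 6 fell was compared only for splits of 2 groups, so it is not known for the large splits of the other comparisons. The source of the splits raised by the term is not settled.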
